A study of Mus musculus with 22 samples.

How the data were processed

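Mouse kidneys of strain C57BL/6 were studied after ligation of the left ureter or after a sham operation, and RNA was extracted with Trizol, per the labels' protocols. Kidney RNA was labelled with Cy5 and a mouse universal reference RNA with Cy3, with T7 promoter priming and MMLV reverse transcriptase, and both were put on one array, per the labels. The dyes had the same orientation on all 22 arrays. The single table of the series holds 45220 spots for the 22 arrays, of which 45018 have a value.

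The deposited values were read as log10 ratios of kidney over reference RNA, a unit inferred from the values because the labels do not state it. They ran from -3.11 to 4, and the median of every array as deposited was exactly 0 with the exact zeros included. The scanner software, background correction, dye normalization and centring are not given in the sources used here. Each array held 5147 to 9271 values of exactly 0, or 11.4% to 20.6% of its spots, with 6628 ± 803 (SD) on the 9 sham and 6418 ± 1070 on the 13 obstructed arrays. An exact 0 was read as a spot without a measured ratio and treated as missing, and an alternative kept the zeros as ratios of 1. The design had assumed log2 ratios, so the values were multiplied by 3.32, the log2 of 10, and the test was kept. The direction of the ratio rests on the dyes given in the labels and on genes of the kidney lying far above 0.

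Between 35747 and 39871 spots of an array had a measured ratio. For arrays the number of replicates limits the precision, and signal over background could not be examined since intensities were not analysed here. Annotation of the platform gave 1 gene for 33653 probes, several for 56 and none for 11511. Probes with a value on at least 18 of the 22 arrays and in at least 1 replicate of each group were kept, the median of each array was subtracted and the probes of a gene were averaged, leaving 17039 genes. Of these, 7303 had over 1 probe, and of the 3969 of them called over all days 42 had probes called in opposite directions. Probes naming no gene or several stayed out of the gene tests and were tested by themselves.

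Samples were grouped by day and operation as the labels give them. The sham arrays S03L and S03R of day 1 share a number and were averaged to 1 replicate, which left 21 replicates, with 2 sham at each day and 3, 3, 3 and 4 obstructed. The letters L and R that end the sample names are not explained in the labels, and the 3 arrays marked R are all sham. The description of each array names an image folder, the only hint of a batch: folder 1 holds S06R, S22L, S19L and S21L and folder 2 the other 18. The sex of the animals was not given; Xist and Y-linked genes showed both sexes among the mice.

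A single limma fit of 8 group means used all arrays, so that all groups share an estimate of the spread, with eBayes and Benjamini-Hochberg adjustment over the genes at 0.05. Contrasts were obstructed minus sham at each day, the mean of the 4 daily differences, the day 9 minus the day 1 difference, and moderated F tests of the differences between days in the effect, in obstructed and in sham kidneys. In all, 35 gene lists for kidney cell types, neighbouring tissue and pathways were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated from the residuals. A list count adjusted over the list alone stands beside that over all genes. List means were also compared by a permutation test that moved the sham and obstructed labels within days over all arrangements. For the list tests and list means, missing gene values, 1667 over all genes, were filled with the mean of their own group. This was done before labels were moved, so the permutation test is exact only in using every arrangement.

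The groups, tests, lists, most alternatives and the rule for naming genes were set before the data were examined. For genes over all days or at a day, that rule required a pass and all obstructed replicates on one side of the sham replicates of the same day. For day 9 minus day 1 it required a pass alone, and for list members and sham genes neither. It named the 8 largest rises and 8 largest falls over all days, the 6 of each at each day and for day 9 minus day 1, the 4 members of lowest p of each list described, and the 6 of lowest p in sham kidneys. It added 18 fixed genes of tubular injury, fibrosis and transport whatever their result, of which Spp1 and Cd68 had no tested value. Clone and predicted locus names were passed over, and genes of the rule that are not printed are in the counts.

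Alternatives fixed beforehand were values with no subtraction of the median, quantile normalization, stricter and looser filters on missing values, each probe by itself, array weights, robust eBayes, a 2-fold minimum, an additive model, S03L and S03R as separate replicates, arrays marked L alone, the image folder as a block and within each folder, each day fitted by itself, fry in place of camera, and each replicate left out in turn. Chosen after seeing the data were zeros kept as values, Xist as a covariate, arrays with Xist above 0 alone, both S03 arrays left out, and arrays S06R, S08L, S09L and S21L left out together.

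The fit and the list test were tried on simulated values of the same design, without the normalization and filters. Of 17039 genes, 67, 67 and 66 were changed by a log2 of 0.5, 1 and 2, a far smaller share than was called in the real data. For the mean over days, 56.7% of genes given a log2 change of 0.5 were called, 91.0% of those given 1 and 98.5% of those given 2, with 7 unchanged genes called. At day 1 the shares were 20.9%, 56.7% and 87.9%, and for day 9 minus day 1 4.48%, 32.8% and 81.8%. Of 35 simulated lists of unchanged genes 0 were called by camera with limma values, and a list of 20 genes raised by a log2 change of 1 was called. The simulated genes varied independently, so this cannot show how often camera at the preset correlation calls unchanged lists whose genes vary together. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.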

Results

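Gene expression was measured in mouse kidneys after ligation of the left ureter, which blocks urine outflow, and after a sham operation in which the ureter was dissected but left open. Kidneys were taken 1, 2, 5 and 9 days later and each RNA sample was compared with a common mouse reference RNA on a 2-colour oligonucleotide array. The 22 arrays were 3, 2, 2 and 2 sham and 3, 3, 3 and 4 obstructed at days 1, 2, 5 and 9. A pair of sham day 1 arrays carried the same number, S03L and S03R, read here as 1 animal, and was averaged, leaving 21 replicates, of which 8 were sham and 13 obstructed. Each array gave a ratio at 35747 to 39871 of 45220 spots, and 17039 genes were tested. Differences below are log2 ratios, obstructed minus sham, ± the standard error of the limma fit, in which the number of arrays sets the precision; the log base of the deposited values was inferred. Largest and most refer to genes that the naming rule allows.

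The comparison of obstructed with sham kidneys of the same day, averaged over the 4 days, asks which genes a blocked ureter changes on average. The daily tests called 8669 genes on 1 or more days, 77 of them up on one day and down on another. The lists of tubular injury, immediate early, chemokine and cytokine, macrophage and matrix genes passed as higher in obstructed kidneys, and those of oxidative phosphorylation, fatty acid oxidation and proximal tubule genes as lower, by camera at a preset correlation. Of the 26 lists that passed so, 0 passed with a correlation estimated from the data. Lcn2, the iron-siderophore carrier that injured tubules secrete, rose by 4.92 ± 0.24, and Il6, an inflammatory cytokine, by 5.48 ± 0.62. Slc22a29, of the organic anion transporter family, fell, with a difference of -2.87 ± 0.20, and Cox5a, a subunit of cytochrome c oxidase, with one of -1.24 ± 0.05. By limma at a Benjamini-Hochberg adjusted p under 0.05, 9025 genes (53%) changed, 4600 up and 4425 down, of which 1170 up and 551 down by at least 2-fold.

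Among the injury markers, 18 of 21 measured rose and 0 fell (18 and 0 adjusted over the list alone). Their median was 2.15 (camera adjusted p = 1.6e-11, and adjusted p = 0.122 with an estimated correlation). The 2 largest rises were those of Sprr2f, a small proline-rich protein of cornified epithelia, at 5.69 ± 0.30, and Il6. Krt20, an intermediate filament keratin of urothelium and gut, rose by 5.44 ± 0.37, Tnfrsf12a, the receptor of the cytokine TWEAK, by 2.67 ± 0.12, and Cd44, the hyaluronan receptor, by 2.89 ± 0.16. Havcr1, which encodes kidney injury molecule KIM-1, rose by 2.03 ± 0.26, but its 2 probes gave 3.71 and 0.35, and the second did not pass. Of the immediate early genes, 19 of 22 measured rose and 0 fell (19 and 0 adjusted over the list alone). Their median was 1.20 (camera adjusted p = 1.43e-09, and adjusted p = 0.140 with an estimated correlation). The transcription factors Egr2, Junb, Klf6 and Jun rose by 4.41 ± 0.26, 2.22 ± 0.14, 1.95 ± 0.11 and 1.90 ± 0.10. Of the p53 target, growth arrest and cell death genes, 13 of 20 measured rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.000306, and adjusted p = 0.122 with an estimated correlation). Bbc3 and Pmaip1, BH3-only inducers of apoptosis, rose by 1.33 ± 0.07 and 1.74 ± 0.15.

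Of the chemokines, cytokines and adhesion molecules, 30 of 37 measured rose and 1 fell (30 and 1 adjusted over the list alone). Their median was 1.76 (camera adjusted p = 2.61e-11, and adjusted p = 0.122 with an estimated correlation). Cxcl5 and Cxcl1, neutrophil-attracting chemokines, rose by 4.80 ± 0.27 and 4.21 ± 0.28, Ccl20, the ligand of CCR6, by 4.63 ± 0.46, Il34, a ligand of the CSF1 receptor, by 2.74 ± 0.15, Icam1, a leukocyte adhesion molecule, by 2.24 ± 0.13, and Ccl2, a monocyte chemoattractant, by 1.69 ± 0.13. Of the monocyte and macrophage markers, 29 of 30 measured rose and 0 fell (29 and 0 adjusted over the list alone). Their median was 1.89 (camera adjusted p = 5.98e-14, and adjusted p = 0.122 with an estimated correlation). Among them were Lgals3, which encodes galectin-3, at 1.89 ± 0.08, Trem2, a lipid-sensing receptor, at 2.16 ± 0.11, Msr1, a scavenger receptor, at 2.31 ± 0.14, and Itgam, the CD11b integrin, at 2.81 ± 0.19. Of the neutrophil markers, 11 of 14 measured rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 5.35e-05, and adjusted p = 0.149 with an estimated correlation). They included Il1r2, the decoy receptor of interleukin 1, at 3.11 ± 0.35 and Csf3r, the receptor of G-CSF, at 2.60 ± 0.32. Of the interferon-stimulated genes, 25 of 28 measured rose and 1 fell (26 and 1 adjusted over the list alone, camera adjusted p = 3.67e-08, and adjusted p = 0.155 with an estimated correlation). They included Psmb8, an immunoproteasome subunit, at 1.34 ± 0.12 and Irf1 at 1.13 ± 0.11. In the complement list 10 of 14 measured rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 0.000736, and adjusted p = 0.184 with an estimated correlation); properdin, Cfp, rose by 1.44 ± 0.11 and the C3a receptor, C3ar1, by 1.58 ± 0.15. Of the MHC class II list, 12 of 14 measured rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 0.000847, and adjusted p = 0.259 with an estimated correlation). They included the invariant chain, Cd74, at 1.27 ± 0.16. For T and NK cells 15 of 21 measured rose and 0 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.00387, and adjusted p = 0.331 with an estimated correlation). They included Il7r, the receptor of interleukin 7, at 2.27 ± 0.25. The B cell and plasma cell list did not pass (camera adjusted p = 0.160), although 5 of 12 measured rose and 0 fell (5 and 0 adjusted over the list alone).

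Of the extracellular matrix and collagen genes, 31 of 34 measured rose and 0 fell (32 and 0 adjusted over the list alone). Their median was 1.28 (camera adjusted p = 8.15e-12, and adjusted p = 0.155 with an estimated correlation). The fibrillar collagens Col1a1, Col1a2 and Col3a1 rose by 2.60 ± 0.32, 2.23 ± 0.23 and 2.26 ± 0.26, and fibronectin, Fn1, by 0.96 ± 0.13. Among the remodelling enzymes and inhibitors 12 of 17 measured rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000200, and adjusted p = 0.149 with an estimated correlation). Timp1, an inhibitor of metalloproteinases, rose by 3.24 ± 0.21, the metalloproteinase Mmp7 by 3.19 ± 0.22 and Adamts1, a secreted protease, by 2.36 ± 0.13. Of the fibroblast, pericyte and myofibroblast markers, 15 of 19 measured rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 6.84e-06, and adjusted p = 0.140 with an estimated correlation). They included Thy1, a fibroblast surface protein, at 2.36 ± 0.17, smooth muscle actin, Acta2, at 1.58 ± 0.13 and Tagln, which encodes SM22, at 2.07 ± 0.16. Vimentin, Vim, rose by 1.03 ± 0.13, with 1 probe at 1.90 and the other at 0.06, which did not pass. In the TGF-beta list 16 of 22 measured rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 0.000235, and adjusted p = 0.122 with an estimated correlation). Tgfb1 rose by 1.16 ± 0.11 and Tgfbi, a secreted target of the pathway, by 2.05 ± 0.16, while Bmp7, a tubular growth factor that opposes it, fell, at -1.15 ± 0.06. Of the Wnt and epithelial-mesenchymal transition regulators, 10 of 18 measured rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00954, and adjusted p = 0.221 with an estimated correlation). They included the repressor Snai1 at 0.94 ± 0.09. Of the cell cycle genes 30 of 35 measured rose and 2 fell (30 and 2 adjusted over the list alone, camera adjusted p = 2.91e-05, and adjusted p = 0.420 with an estimated correlation). Mcm4 and Mcm7, of the replicative helicase, rose by 1.10 ± 0.14 and 0.84 ± 0.13, and Cks2, a cyclin-dependent kinase subunit, fell, at -0.58 ± 0.10.

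All of the oxidative phosphorylation genes fell: 0 of 39 measured rose and 39 fell (0 and 39 adjusted over the list alone). Their median was -1.05 (camera adjusted p = 1.25e-25, and adjusted p = 0.122 with an estimated correlation). Cox5a had a ratio to the reference of 2.51 ± 0.11 (SD, n = 2) in sham and 0.69 ± 0.14 (SD, n = 4) in obstructed kidneys at day 9. Uqcrc2 and Uqcrfs1, of respiratory complex III, gave -1.05 ± 0.06 and -1.28 ± 0.07. Ndufs3, of complex I, fell from 1.89 ± 0.12 (SD, n = 2) to 0.53 ± 0.15 (SD, n = 4) at day 9. In the tricarboxylic acid cycle list 0 of 18 measured rose and 18 fell (0 and 18 adjusted over the list alone, camera adjusted p = 3.68e-12, and adjusted p = 0.122 with an estimated correlation), with malate dehydrogenase, Mdh2, at -1.05 ± 0.07 and succinate dehydrogenase subunit Sdhb at -1.36 ± 0.09. In the fatty acid oxidation and peroxisome list 0 of 25 measured rose and 21 fell (0 and 21 adjusted over the list alone, camera adjusted p = 8.76e-10, and adjusted p = 0.122 with an estimated correlation). Acaa2, the thiolase of the last step of beta-oxidation, gave -1.67 ± 0.11, and Hadh and Etfa, of the same pathway, -1.13 ± 0.07 and -0.99 ± 0.06. The glycolysis list did not pass (camera adjusted p = 0.406; median -0.11, mean 0.03): 4 of 16 measured rose and 6 fell (4 and 6 adjusted over the list alone), with the lactate exporter Slc16a3 up by 1.51 ± 0.16 and Pfkm, muscle phosphofructokinase, down, at -0.88 ± 0.09. The NRF2 and oxidative stress list did not pass either (camera adjusted p = 0.239; median -0.32, mean 0.03), since its members moved both ways: 7 of 24 measured rose and 12 fell (7 and 14 adjusted over the list alone). The mitochondrial superoxide dismutase Sod2 and catalase, Cat, fell, at -1.29 ± 0.08 and -1.21 ± 0.11, and the phagocyte oxidase subunits Ncf1 and Ncf4 rose by 1.77 ± 0.15 and 1.58 ± 0.12.

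Of the proximal tubule genes, 1 of 41 measured rose and 34 fell (1 and 36 adjusted over the list alone). Their median was -0.66 (camera adjusted p = 2.96e-09, and adjusted p = 0.122 with an estimated correlation). Slc7a8, an amino acid exchanger, gave -1.45 ± 0.09, Dpys, an enzyme of pyrimidine breakdown, -2.13 ± 0.19, Ass1, of arginine synthesis, -1.70 ± 0.18 and Slc34a1, the main phosphate transporter, -0.38 ± 0.08, which did not pass after quantile normalization (-0.04). Of the thick ascending limb genes 0 of 12 measured rose and 9 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.000235, and adjusted p = 0.122 with an estimated correlation). They included Egf, the growth factor precursor made there, at -1.32 ± 0.11 and the cotransporter Slc12a1 at -1.46 ± 0.15. Umod, uromodulin, of the same segment, did not pass at -0.17 ± 0.09, and quantile normalization turned its sign (0.12), while it passed as lower without subtraction of array medians (-0.22) and without obstructed replicate S19L (-0.21). In the distal convoluted tubule 0 of 10 measured rose and 9 fell (0 and 9 adjusted over the list alone, camera adjusted p = 0.000474, and adjusted p = 0.122 with an estimated correlation). They included the sodium-calcium exchanger Slc8a1 at -1.32 ± 0.13. In collecting duct principal cells 1 of 13 measured rose and 9 fell (1 and 11 adjusted over the list alone, camera adjusted p = 0.0130, and adjusted p = 0.173 with an estimated correlation). They included water channels Aqp2 and Aqp3 at -0.59 ± 0.08 and -0.90 ± 0.13. In intercalated cells 0 of 15 measured rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 0.000235, and adjusted p = 0.173 with an estimated correlation). They included the anion exchanger Slc4a1 at -2.21 ± 0.19. Gatm, of creatine synthesis, Ak4, a mitochondrial adenylate kinase, and Mogat2, an acyltransferase of triglyceride synthesis, were among the 8 largest falls, at -2.52 ± 0.27, -2.37 ± 0.26 and -2.31 ± 0.20. So were Sycn, a zymogen granule protein, Elavl3, an RNA-binding protein of neurons, and Pdzrn4, at -2.69 ± 0.16, -2.64 ± 0.43 and -2.33 ± 0.22. In the renin-angiotensin list 1 of 10 measured rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.0102, and adjusted p = 0.122 with an estimated correlation); aminopeptidase N, Anpep, gave -1.03 ± 0.14. Kap, an androgen-regulated proximal tubule gene, fell, at -0.42 ± 0.13, but gave 0.030 after quantile normalization.

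The podocyte list (camera adjusted p = 0.131) and the endothelial list (camera adjusted p = 0.835) did not pass: among podocyte genes 2 of 13 measured rose and 6 fell (2 and 6 adjusted over the list alone), and among endothelial genes 2 of 19 measured rose and 3 fell (2 and 2 adjusted over the list alone). Of neighbouring tissue, the urothelium and ureter list passed: 6 of 10 measured rose and 0 fell (6 and 0 adjusted over the list alone). Their median was 0.65 (camera adjusted p = 0.0191, and adjusted p = 0.380 with an estimated correlation), and the basal keratin Krt14 rose by 2.44 ± 0.21. It no longer passed (camera adjusted p = 0.0920) when arrays S06R, S08L, S09L and S21L were left out together. The adipose list (camera adjusted p = 0.842), the red blood cell list (camera adjusted p = 0.744) and the sex-specific list (camera adjusted p = 0.853) did not pass. The adrenal list did not either (camera adjusted p = 0.417, and 0.0307 without sham replicate S03). By a two-sided permutation test within days, 28 of the 35 lists had an adjusted p under 0.05, and 18 reached 6.67e-05, the smallest p that its 15000 arrangements can give. Unlike camera, it does not compare a list with the other genes. The podocyte (permutation adjusted p = 0.000233) and B cell (0.00667) lists passed it, and the endothelial list did not (0.820).

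In all, 1367 genes were higher in every obstructed replicate than in every sham replicate of the same day on all 4 days and 1492 were lower, where chance separates a gene one way at a single day in 10% of cases, or 6.67% at day 9. With the scanner image folder, which may or may not mark a batch, as a block, 8957 genes changed and the same 26 lists passed, but with quantile normalization the thick ascending limb (camera adjusted p = 0.0560), principal cell (0.391) and renin-angiotensin (0.121) lists did not. With each replicate left out in turn, between 8368 and 9205 genes were called, while the balance of the counts turned with the scaling: 4057 genes were up and 5193 down without subtraction of array medians, and 3563 up and 5003 down after quantile normalization.

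**Figure D1:**
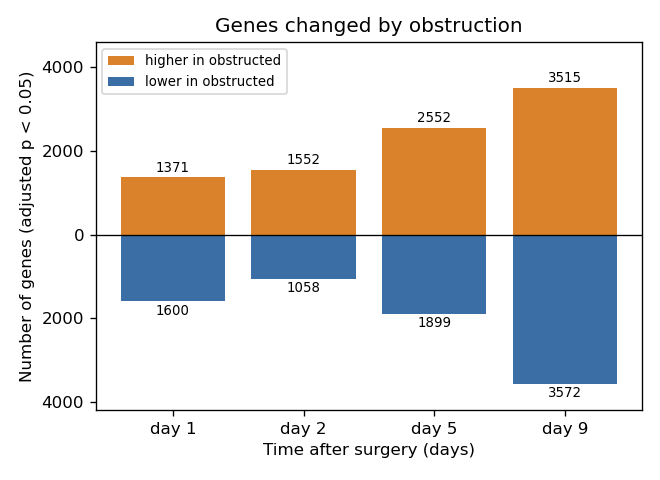
Number of genes higher (bars above 0) and lower (bars below 0) in obstructed than sham kidneys at each day, by limma at an adjusted p under 0.05 of 17039 genes tested. Counts up ran from 1371 at day 1 to 3515 at day 9 and counts down from 1058 at day 2 to 3572 at day 9.

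One day after ligation, the question is which genes respond first. The injury and immediate early lists passed as higher and those of oxidative phosphorylation and the proximal tubule as lower, and matrix and fibroblast lists did not pass while those of matrix remodelling and TGF-beta did. Of the 20 lists that passed at day 1, 1, the injury list, also passed with an estimated correlation. Krt20, Ccl20 and Sprr2f rose most, by 6.18 ± 0.76, 6.16 ± 0.94 and 6.04 ± 0.60, and Lcn2 rose by 5.04 ± 0.48, from a ratio of -0.72 ± 1.22 (SD, n = 2) in sham to 4.32 ± 0.39 (SD, n = 3) in obstructed kidneys. Slc22a22, a prostaglandin-specific organic anion transporter, fell most, at -4.08 ± 0.96. By limma, 2971 genes changed, 1371 up and 1600 down.

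Of the injury markers at day 1, 16 of 21 measured rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.97 (camera adjusted p = 1.59e-15); this list alone still passed with an estimated correlation (adjusted p = 0.0458). Tnfrsf12a rose by 3.72 ± 0.25. Of the immediate early genes 15 of 22 measured rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 4.35e-12, and adjusted p = 0.169 with an estimated correlation). They included Atf3, a stress-induced transcription factor, at 3.28 ± 0.36 and Myc at 2.42 ± 0.28. Among p53 and growth arrest genes 10 of 20 measured rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.22e-06, and adjusted p = 0.111 with an estimated correlation). They included Gadd45a at 1.65 ± 0.25. Of the chemokine and cytokine genes 15 of 37 measured rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 1.94e-08, and adjusted p = 0.169 with an estimated correlation). Il6 rose by 5.61 ± 1.25 and Cxcl1 went from a ratio of -5.08 ± 0.59 (SD, n = 2) to -0.88 ± 0.65 (SD, n = 3). Of the macrophage genes 6 of 30 measured rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 6.67e-05, and adjusted p = 0.403 with an estimated correlation). Cd14, the co-receptor for endotoxin, and Arg1, arginase, rose by 4.68 ± 0.62 and 3.89 ± 0.99. Mt2, a metallothionein, Hmox1, heme oxygenase, and Gclc, of glutathione synthesis, rose by 4.12 ± 0.56, 2.40 ± 0.45 and 1.92 ± 0.33, although the NRF2 list did not pass (camera adjusted p = 0.0636). Grp, a neuropeptide, rose by 5.03 ± 0.95. Of the oxidative phosphorylation genes 0 of 39 measured rose and 32 fell (0 and 36 adjusted over the list alone, camera adjusted p = 4.78e-19, and adjusted p = 0.169 with an estimated correlation). They included Ndufb10 at -1.08 ± 0.17. In the proximal tubule list 0 of 41 measured rose and 10 fell (0 and 14 adjusted over the list alone, camera adjusted p = 9.83e-06, and adjusted p = 0.257 with an estimated correlation). Cyp2f2, a cytochrome P450, Elavl3, Slc7a13, an amino acid transporter, Slitrk1, a neuronal membrane protein, and Slc16a7, a monocarboxylate transporter, fell, at -3.91 ± 1.22, -3.66 ± 0.86, -3.33 ± 0.97, -3.16 ± 0.54 and -3.09 ± 0.46; 1 of the 2 probes of Slc16a7 gave -1.47 and did not pass. Cyp2f2 did not pass without obstructed replicate S02L, S05L or S38L or sham array S03R, nor did Slc7a13 without S02L or S05L. Neither passed after quantile normalization, and Cyp2f2 did not with the Xist covariate. The matrix list had a median of 0.21 (camera adjusted p = 0.0745), where 2 of 34 measured rose and 0 fell (0 and 0 adjusted over the list alone). The fibroblast list had a median of 0.10 (camera adjusted p = 0.383), where 0 of 19 measured rose and 0 fell (0 and 0 adjusted over the list alone). In the matrix remodelling list 5 of 17 measured rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0296, and adjusted p = 0.418 with an estimated correlation), and in the TGF-beta list 7 of 22 measured rose and 1 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0296, and adjusted p = 0.391 with an estimated correlation). The adrenal list, of a gland beside the kidney, was lower in obstructed kidneys (camera adjusted p = 0.00489, and adjusted p = 0.402 with an estimated correlation), and 7 of its 8 genes were highest in sham replicate S06R: the mean of the list there was 3.48 against 0.52 in the other sham replicate.

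Without sham replicate S06R 1100 genes were called at day 1 and 17 of the 23 genes named for this day passed (not Slc22a22 at -3.79, Il6 at 5.71, Arg1 at 3.42, Elavl3 at -2.73, Slc7a13 at -3.19 or Cyp2f2 at -1.34, which gave -6.49 without sham replicate S03), and without subtraction of array medians 1623 genes were up and 1391 down. Other fits gave 1182 genes with the arrays marked L alone, 1185 with 4 doubted arrays left out, 158 when only that day's arrays, S06R included, were fitted, 2080 with the image folder as a block, 1016 up and 1064 down, where Arg1 (3.17), Cyp2f2 (-2.51) and Slc7a13 (-3.28) did not pass, and 928 within folder 2, with 1 sham and 3 obstructed replicates.

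At day 2, the cell cycle, matrix and macrophage lists passed as higher in obstructed kidneys, and of the 22 lists that passed 0 did so with an estimated correlation. Spink12, a serine protease inhibitor, Cstdc6, of the stefin A family of cysteine protease inhibitors, and Cxcl3, a neutrophil-attracting chemokine, were among the largest rises, at 4.74 ± 0.74, 4.77 ± 0.64 and 4.64 ± 1.40. Inmt, an indole methyltransferase, and Sycn fell most, at -3.02 ± 0.71 and -2.98 ± 0.32. By limma, 2610 genes changed, 1552 up and 1058 down.

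Of the cell cycle genes at day 2, 18 of 35 measured rose and 0 fell (30 and 0 adjusted over the list alone). Their median was 1.22 (camera adjusted p = 6.28e-11, and adjusted p = 0.239 with an estimated correlation). Aurka, a mitotic kinase, rose by 1.45 ± 0.32, Mcm4 by 1.49 ± 0.28 and cyclin E, Ccne1, by 1.09 ± 0.25. Of the matrix genes 20 of 34 measured rose and 0 fell (25 and 0 adjusted over the list alone, camera adjusted p = 5.39e-11, and adjusted p = 0.214 with an estimated correlation). Col1a1 rose by 2.49 ± 0.64 and Col8a1 by 2.51 ± 0.42. Of the fibroblast genes 11 of 19 measured rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 1.74e-05, and adjusted p = 0.188 with an estimated correlation). Acta2 rose by 2.05 ± 0.27, though 1 of its 13 probes, at 0.71, did not pass. Of the macrophage genes 18 of 30 measured rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 2.6e-13, and adjusted p = 0.150 with an estimated correlation). They included Msr1 at 3.12 ± 0.29. Cxcl10, an interferon-induced chemokine, rose by 4.40 ± 0.46. Of the interferon-stimulated genes 13 of 28 measured rose and 0 fell (19 and 1 adjusted over the list alone, camera adjusted p = 6.85e-08, and adjusted p = 0.213 with an estimated correlation). Among neutrophil genes 7 of 14 measured rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.18e-05, and adjusted p = 0.176 with an estimated correlation). They included Retnlg, a resistin-like protein, at 4.35 ± 1.00. Of the complement genes 6 of 14 measured rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00221, and adjusted p = 0.239 with an estimated correlation). They included C4b at 2.88 ± 0.63, or 1.74 without sham replicate S39R, when it did not pass. Of the oxidative phosphorylation genes 0 of 39 measured rose and 38 fell (0 and 38 adjusted over the list alone, camera adjusted p = 2.38e-32, and adjusted p = 0.0766 with an estimated correlation). Of the intercalated cell genes 0 of 15 measured rose and 7 fell (0 and 11 adjusted over the list alone, camera adjusted p = 1.28e-06, and adjusted p = 0.150 with an estimated correlation). They included Insrr, a receptor of alkali, at -1.24 ± 0.22. Hpd, of tyrosine breakdown, Fa2h, a fatty acid hydroxylase, Grin3a, a glutamate receptor subunit, and Mixl1, a homeobox gene, fell, at -2.50 ± 0.50, -2.57 ± 0.75, -2.33 ± 0.44 and -2.67 ± 0.48. Without obstructed replicate S04L Fa2h gave -1.36. With zeros kept as values Grin3a (-1.14) and Mixl1 (-1.39) did not pass. Kap fell, at -0.84 ± 0.27, but did not pass after quantile normalization (-0.27), with the arrays marked L alone (-0.82), with zeros kept, or with most of the replicates left out in turn.

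Fewer genes were called at day 2 without sham replicate S08L (1004), sham replicate S39R (1314) or obstructed replicate S18L (1547), and Col1a1, Cxcl3, Fa2h and Kap did not pass without either sham replicate, nor did Aurka, C4b, Grin3a and Retnlg without S39R or Ccne1, Hpd and Inmt without S08L. The arrays marked L alone gave 1239, 4 arrays left out 1145 and quantile normalization 1693, 855 up and 838 down, where Aurka, Ccne1, Cxcl3, Fa2h and Kap did not pass; all day 2 arrays were in image folder 2, and the blocked count was 2607.

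At day 5, the macrophage, MHC class II, matrix and urothelial lists passed as higher and that of oxidative phosphorylation as lower, and of the 24 lists that passed 0 did so with an estimated correlation. Krt20 and Sprr2f rose by 6.91 ± 0.76 and 6.22 ± 0.60, Cxcl5 and Cxcl1 by 5.49 ± 0.55 and 5.26 ± 0.56 and Egr2 by 5.15 ± 0.53. Slc22a29, Grpr, a receptor of gastrin-releasing peptide, Ccdc169 and Bbox1, of carnitine synthesis, were among the largest falls, at -3.32 ± 0.40, -3.09 ± 0.60, -2.85 ± 0.46 and -2.76 ± 0.62. By limma, 4451 genes changed, 2552 up and 1899 down.

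Of the macrophage genes at day 5, 28 of 30 measured rose and 0 fell (28 and 0 adjusted over the list alone). Their median was 2.45 (camera adjusted p = 2.5e-17, and adjusted p = 0.123 with an estimated correlation). Trem2, Ctss, which encodes the lysosomal protease cathepsin S, Fcgr1, an Fc receptor, and Adgre1, which encodes the F4/80 antigen, rose by 3.12 ± 0.22, 3.81 ± 0.44, 3.35 ± 0.40 and 2.61 ± 0.40. Of the MHC class II genes 8 of 14 measured rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 0.000323, and adjusted p = 0.264 with an estimated correlation). Cd74 rose by 2.37 ± 0.33. Of the T and NK cell genes 5 of 21 measured rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.00648, and adjusted p = 0.390 with an estimated correlation). They included Cd3d, of the T cell receptor complex, at 2.72 ± 0.73. Vcam1, an adhesion molecule, rose by 3.86 ± 0.37, though 1 of its 3 probes, at 1.69, did not pass, and Wfdc21, of the neutrophil list, by 5.13 ± 1.05. Of the matrix genes 28 of 34 measured rose and 0 fell (28 and 0 adjusted over the list alone, camera adjusted p = 1.02e-11, and adjusted p = 0.208 with an estimated correlation). They included Col18a1 and Fbln2, of basement membranes and elastic fibres, at 1.58 ± 0.20 and 1.26 ± 0.21. Of the remodelling genes 10 of 17 measured rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 6.11e-05, and adjusted p = 0.168 with an estimated correlation). They included Mmp14 at 2.35 ± 0.30. Of the urothelial genes 6 of 10 measured rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000549, and adjusted p = 0.246 with an estimated correlation). They included Krt5 at 1.30 ± 0.28. Agtr2, the type 2 angiotensin receptor, rose by 2.78 ± 0.67. In the renin-angiotensin list as a whole 1 of 10 measured rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0297, and adjusted p = 0.178 with an estimated correlation). Of the oxidative phosphorylation genes 0 of 39 measured rose and 39 fell (0 and 39 adjusted over the list alone, camera adjusted p = 4.71e-35, and adjusted p = 0.0583 with an estimated correlation). Of the fatty acid oxidation genes 0 of 25 measured rose and 17 fell (0 and 19 adjusted over the list alone, camera adjusted p = 2.86e-09, and adjusted p = 0.168 with an estimated correlation). Among the proximal tubule genes at day 5 1 of 41 measured rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.000177, and adjusted p = 0.266 with an estimated correlation).

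At day 5 the direction of the counts depended on the scaling: without subtraction of array medians 1908 genes were up and 2877 down, as the median of all genes moved to -0.11, and after quantile normalization 1917 were up and 2374 down. Without sham replicate S22L 2618 genes were called, with 18 of the 22 named for this day (not Agtr2, Bbox1, Cd3d or Krt5), and without sham replicate S32L 2934, the blocked count was 4482, and within folder 1 (1 sham and 2 obstructed replicates) 2175 and within folder 2 (1 of each) 1279 were called, and 2532 when only that day's arrays were fitted.

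At day 9 the response was widest, with 7087 genes changed by limma, 3515 up and 3572 down. The matrix, fibroblast and macrophage lists passed as higher than in sham kidneys, and the proximal tubule and oxidative phosphorylation lists as lower, and of the 27 lists that passed 0 did so with an estimated correlation. Cxcl5 rose by 6.94 ± 0.52, Lcn2 by 5.53 ± 0.46 and Olr1, a receptor for oxidized lipoprotein, by 5.25 ± 0.61. Col1a1 rose by 4.18 ± 0.61, from a ratio of -2.20 ± 1.74 (SD, n = 2) in sham to 1.98 ± 0.52 (SD, n = 4) in obstructed kidneys. C8a, of the terminal complement complex, Slc22a29, Cyp4f14, a cytochrome P450, Klk1b16, a kallikrein, Dpys and Fancd2os fell most, at -4.63 ± 1.06, -4.05 ± 0.38, -3.75 ± 0.84, -3.64 ± 0.35, -3.56 ± 0.37 and -3.50 ± 0.65.

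Of the matrix genes at day 9, 32 of 34 measured rose and 0 fell (33 and 0 adjusted over the list alone). Their median was 2.21 (camera adjusted p = 3.23e-15, and adjusted p = 0.132 with an estimated correlation). Bgn, biglycan, rose by 2.99 ± 0.36, Mgp, matrix Gla protein, by 4.27 ± 0.57 and Tnc, tenascin C, by 2.85 ± 0.49. Of the fibroblast genes 15 of 19 measured rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 8.15e-08, and adjusted p = 0.110 with an estimated correlation). Thy1 rose by 3.62 ± 0.33 and Tagln by 3.08 ± 0.31. Of the TGF-beta genes 14 of 22 measured rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 4.13e-05, and adjusted p = 0.110 with an estimated correlation). They included Ltbp2, a latent TGF-beta binding protein, at 3.16 ± 0.24 and Inhba, an activin subunit, at 3.15 ± 0.35. Of the Wnt and transition regulators 12 of 18 measured rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 5.28e-05, and adjusted p = 0.110 with an estimated correlation). They included Dkk3 at 2.55 ± 0.23. Of the macrophage genes at day 9 27 of 30 measured rose and 0 fell (28 and 0 adjusted over the list alone, camera adjusted p = 4.49e-15, and adjusted p = 0.110 with an estimated correlation). They included Lyz2, lysozyme, at 3.89 ± 0.44, C1qb, of complement C1q, at 3.15 ± 0.47 and Tyrobp, a signalling adaptor, at 3.01 ± 0.29. Klrb1c, the NK1.1 antigen, and Ighm, the IgM heavy chain, rose by 2.07 ± 0.51 and 1.88 ± 0.40. The T and NK cell list passed (camera adjusted p = 0.00209, and adjusted p = 0.291 with an estimated correlation) and the B cell list did not (camera adjusted p = 0.0724). Of the interferon-stimulated genes 23 of 28 measured rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 1.91e-08, and adjusted p = 0.144 with an estimated correlation). In the proximal tubule list 0 of 41 measured rose and 32 fell (0 and 35 adjusted over the list alone, camera adjusted p = 2.02e-10, and adjusted p = 0.110 with an estimated correlation). They included Cubn, the endocytic receptor cubilin, at -2.08 ± 0.30 and Napsa, an aspartic protease, at -1.98 ± 0.24. Of the fatty acid oxidation genes 0 of 25 measured rose and 23 fell (0 and 23 adjusted over the list alone, camera adjusted p = 6.52e-11, and adjusted p = 0.110 with an estimated correlation). Of the oxidative phosphorylation genes 0 of 39 measured rose and 39 fell (0 and 39 adjusted over the list alone, camera adjusted p = 1.24e-26, and adjusted p = 0.110 with an estimated correlation). In the NRF2 list 4 of 24 measured rose and 11 fell (5 and 11 adjusted over the list alone, camera adjusted p = 0.0200, and adjusted p = 0.329 with an estimated correlation). They included the glutathione transferase Gsta1 at -2.28 ± 0.21. Aqp2 fell, at -1.18 ± 0.15.

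Without sham replicate S33L 4456 genes were called at day 9, with all 27 named for this day. All day 9 arrays were in folder 2 and the blocked count was 7167, while without subtraction of array medians 3126 genes were up and 4159 down, and quantile normalization, which moved the median of all genes to -0.12, gave 2811 up and 4020 down.

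**Figure D2:**
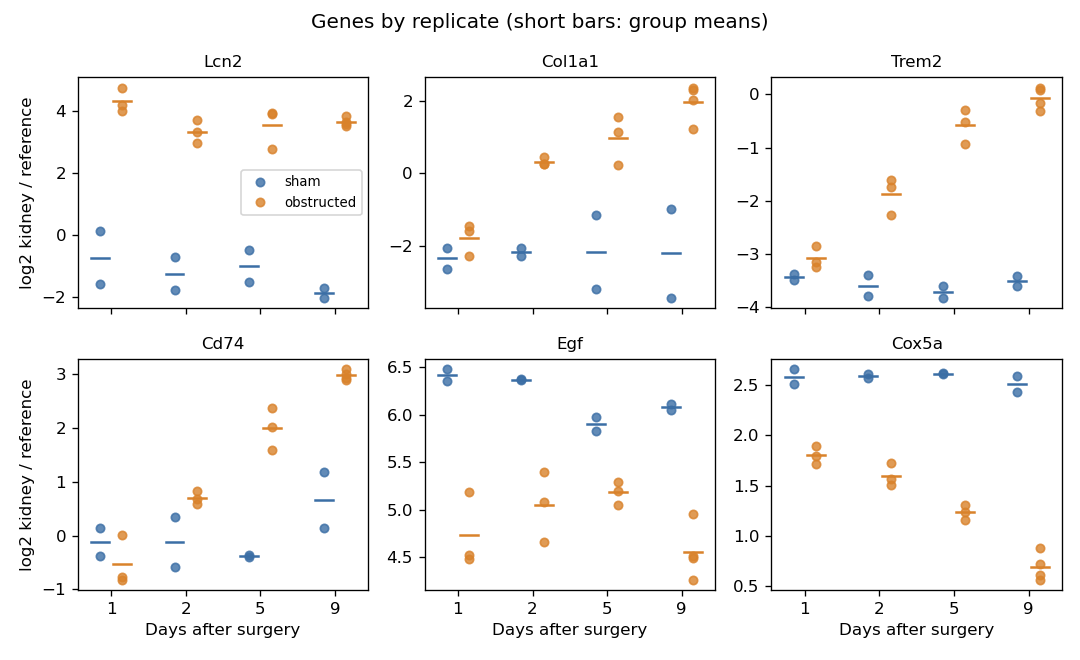
Log2 ratio of kidney to reference RNA, with the array median subtracted, of 6 genes in each sham (blue) and obstructed (orange) replicate by day after surgery; short bars are group means of 2 sham and 3 or 4 obstructed replicates. Lcn2 was 5.04 higher at day 1 and 5.53 at day 9, while Col1a1 was 0.57 and 4.18 higher.

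The 4 days were compared with each other to ask whether the effect of obstruction changed with time. For the difference at day 9 minus that at day 1, the matrix, fibroblast, macrophage and MHC class II lists passed as positive and the NRF2 and oxidative phosphorylation lists as negative, and of the 20 lists that passed 0 did so with an estimated correlation. Cxcl5 gained 3.88 ± 0.76, Lyz2 4.15 ± 0.64, Mmp14, a membrane metalloproteinase, 2.90 ± 0.41 and Trem2 3.09 ± 0.30. Gclc, which was up at day 1, lost ground, at -2.60 ± 0.45. By limma, 1994 genes differed between day 9 and day 1, 1235 with a larger and 759 with a smaller value at day 9, and 834 differed between any days, of which 655 had their largest size at day 9.

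In the matrix list 21 of 34 genes (30 adjusted over the list alone) had a larger difference at day 9 and 0 a smaller one, with a median of 1.98 (camera adjusted p = 3.52e-17, and adjusted p = 0.255 with an estimated correlation). They included Col1a1 at 3.61 ± 0.88, Bgn at 2.96 ± 0.53 and Col6a1 at 2.37 ± 0.35. The mean of the matrix list varied widely between the 2 sham replicates of day 9, at -0.79 ± 0.95 (SD), against an SD of 0.08 at day 1. For fibroblasts and macrophages the sham SD was 0.54 and 0.55 at day 9, against 0.16 and 0.02 at day 1. For MHC class II it was 0.28 against 0.29. How far the gains of these lists lean on a single sham replicate was not tested. In the fibroblast list 14 of 19 genes (15 adjusted over the list alone) had a larger difference at day 9, with a median of 2.05 (camera adjusted p = 2.94e-09, and adjusted p = 0.245 with an estimated correlation). Acta2 was at 2.32 ± 0.37, though 1 of its 13 probes, at 0.77, did not pass. Mmp2 and Timp2, a metalloproteinase and an inhibitor, gave 2.88 ± 0.29 and 3.45 ± 0.46, Ltbp2 2.81 ± 0.34 and Dkk3 3.14 ± 0.33. Of the macrophage genes 19 of 30 (22 adjusted over the list alone) were larger at day 9, with a median of 2.05 (camera adjusted p = 2.01e-11, and adjusted p = 0.265 with an estimated correlation). Of the MHC class II genes it was 6 of 14, and 10 adjusted over the list alone (camera adjusted p = 5.59e-06, and adjusted p = 0.266 with an estimated correlation), Cd74 at 2.72 ± 0.45. Of the oxidative phosphorylation genes 22 of 39, and 35 adjusted over the list alone, were lower at day 9 than at day 1 relative to sham (camera adjusted p = 6.81e-19, and adjusted p = 0.245 with an estimated correlation), Cox5a at -1.04 ± 0.15. Of the NRF2 genes 11 of 24 were lower and 3 higher, and 15 and 3 adjusted over the list alone (camera adjusted p = 9.91e-06, and adjusted p = 0.255 with an estimated correlation), Nqo1, a quinone reductase, at -2.13 ± 0.38 and Gsta1 at -2.36 ± 0.31. The injury list (camera adjusted p = 0.257) and the immediate early list (camera adjusted p = 0.559) did not differ between the days by this test, although Tnfrsf12a and Myc were lower at day 9, by differences of -1.15 ± 0.34 and -1.32 ± 0.39. The largest gains were those of Pnma2, Kcnd2, Th, Col8a2, Greb1 and Kcnmb4, at 5.41 ± 0.95, 4.99 ± 1.35, 4.68 ± 1.17, 4.63 ± 0.74, 4.61 ± 1.08 and 4.48 ± 0.95. The largest losses were those of Ly6f, Rab39b, Stra6l, Lrat, Klk1b16 and Scgb1c1, at -3.20 ± 0.60, -3.08 ± 0.63, -3.01 ± 0.71, -2.94 ± 0.81, -2.90 ± 0.51 and -2.83 ± 0.79; with the arrays marked L alone Rab39b gave -1.53 and did not pass. Across genes, which are not independent replicates, differences at day 5 and day 9 correlated at r = 0.846 and those at day 1 and day 9 at r = 0.536. In all, 2213 genes were up at both day 5 and day 9, against 526 if the calls were unrelated. Over the 4 days 528 genes were up and 561 down at every day.

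The count of 1994 fell to 1114 without sham replicate S06R, 1309 without sham replicate S03 and 576 without sham replicate S33L, and that of 834 to 264, 369 and 268; the latter also fell to 428, 412 and 488 without obstructed replicates S34L, S35L and S36L, rose to 1328 without S09L and was 430 with the arrays marked L alone and 500 with the image folder as a block, which gave 1768 for day 9 against day 1 and with which Myc (-1.32), Tnfrsf12a (-1.10), Kcnd2 (4.28) and Lrat (-2.75) kept similar values but did not pass, at adjusted p from 0.0517 to 0.0729. Of the 31 genes named here 25, 24 and 23 passed without S06R, S03 and S33L (Myc, Kcnd2, Lrat and Tnfrsf12a failed without each, Greb1 and Th without S06R or S33L, and Scgb1c1 and Col1a1 without S03 or S33L, Col1a1 giving 3.32 and 2.38, and Stra6l without S03), and without subtraction of medians 1073 genes were larger and 1313 smaller at day 9, with a median over all genes of -0.12, and after quantile normalization 1094 and 1280.

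**Figure D3:**
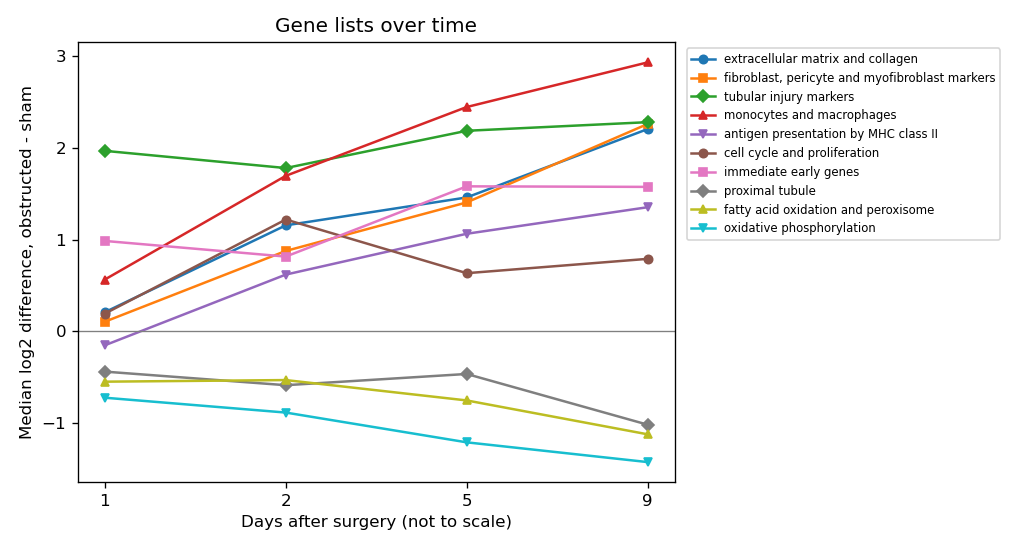
Median log2 difference, obstructed minus sham, of 10 gene lists at days 1, 2, 5 and 9 after surgery; each line is a list. The matrix list went from 0.21 to 2.21 and the macrophage list from 0.56 to 2.94, while oxidative phosphorylation went from -0.73 to -1.43. The 2 sham replicates of day 9 lay far apart on the matrix list, with a mean of -0.79 ± 0.95 (SD). They also differed on the macrophage list, at -0.74 ± 0.55 (SD).

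Obstructed and sham kidneys were also each compared across the 4 days by themselves. In obstructed kidneys 5659 genes differed between days by limma, and 5624 with the image folder as a block. In sham kidneys 0 genes passed an adjusted p under 0.05 in limma while 947 had an unadjusted p under 0.05. The genes of lowest p in sham kidneys were Olfr248 and Olfr702, olfactory receptors, Cpne1, a copine, Coq10b, of coenzyme Q function, Ciart, a circadian repressor, and Cited2, a transcriptional regulator, none of which passed. In simulated data of the same design, 86.4% of genes given a log2 change of 2 at one sham day were called and 11.9% of those given 0.5. Leaving out sham replicate S03 gave 38 genes, S33L 8, S39R 2 and S06R 1, the arrays marked L alone gave 16 and 4 arrays left out 2, and keeping exact zeros gave 1 and an Xist covariate 2.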

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

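The tests of the 3 patterns weighed below were chosen only after the results were seen, while the tests of differences between days were set beforehand.

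Adrenal genes were lower in obstructed than in sham kidneys at day 1, with a difference in list mean of -1.99, and the adrenal list also differed between day 9 and day 1, with a median of 2.14 (camera adjusted p = 0.0125, and adjusted p = 0.483 with an estimated correlation). The list mean was 3.48 on sham array S06R against at most 1.39 on the 20 other replicates, and 7 of the 8 genes, of cortex and medulla alike, were highest there (Star 6.23, Cyp11a1 4.21, Th 3.84 and Pnmt 3.91). Without S06R the day 1 difference was -0.51, so a piece of adrenal gland in that sample may account for most of it. Subtraction of the array median does not account for it, since the difference was -1.94 with no subtraction. Without S06R the sham group of day 1 holds 1 replicate, so the size of any effect of obstruction on such genes stays open. Any other change that tissue of the gland brought to S06R remains in the day 1 values.

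The effect of obstruction at day 9 differed from that at day 1 in 1994 genes, and 834 differed between any days by the F test. Sex of the animals is argued against as the whole cause, since 1274 of the genes were called with the same sign when only arrays with Xist above 0 were fitted. The image folder and the adrenal signal of S06R do not account for all of it either, with 1768 genes called with the folder as a block and 1114 without S06R. The count leaned on single sham replicates, however, and was 576 without S33L, where the sham group of day 9 holds 1 replicate. A growing response of matrix and macrophage genes over time restates part of this pattern, and its cause was not tested. It leaves out the 759 genes with a smaller value at day 9.

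Tubule and mitochondrial genes were lower in obstructed kidneys over all days. A lower share of tubule RNA that raises every other cell type alike is argued against as the only cause. The macrophage list rose by 1.93 (95% interval 1.63 to 2.23) more than the endothelial list. Macrophage genes would also rise further if cells came in, so this cannot decide whether the tubule share fell. Dilution by incoming cells that lowers every resident type alike is likewise argued against as the only cause. The proximal tubule list fell further than the endothelial list, with a difference of -0.69 (-0.87 to -0.51). Subtraction of medians is not the source for the oxidative phosphorylation list, whose median was -1.10 without it. The array medians of measured ratios ran only from -0.163 to 0.00477, so that step could move little. Quantile normalization ended the calls of the thick ascending limb and principal cell lists, while the other tubule lists and oxidative phosphorylation kept theirs. Scaling done before deposit could not be examined. Lower expression in the tubules, a loss of tubule cells that differs by segment, or a change in the endothelium itself could each give these values. So could a lower share of tubule RNA together with incoming cells, whose effects on the endothelial list would oppose each other. Kidney RNA as a whole cannot separate these.

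In the obstructed group of day 9, the only one of 4 replicates, 16 of 201 values (7.96%) had a replicate set apart from the others. Chance gives 5% for a single value, but the values come from the same 4 arrays and are not independent. In each, the gap to the nearest replicate as a share of the whole range exceeded Dixon's critical value for 4 replicates. For the sex-specific list the ratio was 0.972, with S09L at -0.53 and the others from -3.43 to -3.35. S09L was the only day 9 array with Xist below 0 and held the most exact zeros of any array, 9271. Whether either fact explains its other values was not tested. The proximal tubule list gave 0.857, with S09L at 4.83 against 4.18 to 4.27, and the red blood cell list 0.916, with S36L at 4.31 against 4.06 to 4.08. S09L stood above the others in Gatm (0.964), Ass1 (0.932), Hadh (0.917), Mmp7 (0.905), Ncf1 (0.883), Inmt (0.879), Ndufs3 (0.864), Slc22a29 (0.852) and Aurka (0.830), and below them in Tgfb1 (0.843). Inmt was 1.98 on S09L against -0.87 to -0.52, and Slc22a29 was 4.42 against a lowest of 2.75. S36L was high in Cd14 (0.830), S34L low in Olr1 (0.851) and S35L low in Dpys (0.872).

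The following differences between day 9 and day 1 had an adjusted p under 0.05 in the test of the difference itself, although 0 of the 20 list calls remained with an estimated correlation. Among the lists, the medians were 1.98 for matrix, 2.05 for fibroblasts, 2.05 for macrophages, 1.38 for MHC class II, 1.12 for Wnt regulators and 0.90 for urothelium. They were 0.78 for T and NK cells, 0.66 for interferon-stimulated genes, 0.66 for the cell cycle, 0.64 for chemokines, 0.60 for B cells, 0.58 for matrix remodelling, 0.48 for TGF-beta and 0.39 for complement. Below 0 were NRF2 at -1.06, oxidative phosphorylation at -0.72, the tricarboxylic acid cycle at -0.65, fatty acid oxidation at -0.62 and the proximal tubule at -0.42.

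Single genes that gained between day 1 and day 9 were Pnma2 (5.41), Kcnd2 (4.99), Th (4.68), Col8a2 (4.63), Greb1 (4.61), Kcnmb4 (4.48), Lyz2 (4.15), Cxcl5 (3.88), Col1a1 (3.61), Timp2 (3.45), Dkk3 (3.14), Trem2 (3.09), Bgn (2.96), Mmp14 (2.90), Mmp2 (2.88), Ltbp2 (2.81), Cd74 (2.72), Col6a1 (2.37) and Acta2 (2.32). Those that lost were Ly6f (-3.20), Rab39b (-3.08), Stra6l (-3.01), Lrat (-2.94), Klk1b16 (-2.90), Scgb1c1 (-2.83), Gclc (-2.60), Gsta1 (-2.36), Nqo1 (-2.13), Myc (-1.32), Tnfrsf12a (-1.15) and Cox5a (-1.04). Without S06R, where it was highest, Th gave 3.27 and no longer passed (adjusted p = 0.106 in limma), nor did it without S03L (3.96), S33L (4.47) or S39R (4.66). Without S33L Col1a1 gave 2.38 and did not pass either.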

How the results depend on the processing

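Kept zeros, the Xist covariate, arrays with Xist above 0 alone, both S03 arrays left out and 4 arrays (S06R, S08L, S09L and S21L) left out together were chosen after seeing the data. Of the 339 values of counts under the alternatives 289 stayed within 1.5 times the reported count and 50 moved further. For the lists 1074 of 1120 values kept their direction and their side of the threshold, 30 were weaker, 5 stronger and 11 changed direction. Of 7073 values for named genes 6874 stayed the same in both ways, 194 were weaker, 2 stronger and 3 changed direction. Fits with replicates left out gave 186 of the 289 counts and 4971 of the 6874 gene values that stayed. Many of them left out a replicate of a day that the contrast does not use, where little could change. The totals thus say less than the fits without a sham replicate of the same day. No count moved beyond 1.5 times with array medians not subtracted, array weights, robust eBayes, either filter on missing values or S03L and S03R as separate replicates. Fewer replicates enter the fits that leave arrays out, within a folder or at a single day, and a sham group left with 1 replicate is assumed to vary like the others. More items are tested where each probe is tested by itself, and a 2-fold minimum can only lower a count. For the other changes the cause was not tested. Every alternative set beforehand was run. The lists were tested again over all days only, apart from the estimated correlation and fry, which were run for each day too. Counts alone were made again for the filters on missing values, separate S03 arrays, robust eBayes, array weights, the 2-fold minimum, the additive model, single days and single folders. The lists were also not tested again with each probe by itself or with arrays with Xist above 0 alone.

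Testing each probe gave 5132 probes at day 1, 4459 at day 2, 7835 at day 5, 13151 at day 9, 17439 over all days, 10257 between obstructed days and 3388 for day 9 minus day 1. With changes of at least 2-fold the counts were 975, 1048, 1793 and 3094 at the 4 days, 1721 over all days and 1242 for day 9 minus day 1. Quantile normalization gave 1693 genes at day 2. The arrays marked L alone gave 1182 genes at day 1, 1239 at day 2, 430 between days in the effect and 16 between sham days. The image folder as a block gave 500 between days in the effect, folder 2 alone 928 at day 1 and 1279 at day 5, and folder 1 alone 2175 at day 5. Fitting only the arrays of a day gave 158 genes at day 1 and 2532 at day 5. Without the 4 doubted arrays there were 1185 genes at day 1, 1145 at day 2 and 2 between sham days. Between sham days the count was 1 with zeros kept and 2 with the Xist covariate.

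Leaving out each replicate in turn gave 1100 to 3370 genes at day 1, 1004 to 2976 at day 2, 2618 to 4817 at day 5, 4456 to 7417 at day 9 and 8368 to 9205 over all days. It gave 4411 to 5918 between obstructed days, 0 to 38 between sham days, 264 to 1328 between days in the effect and 576 to 2504 for day 9 minus day 1. The lowest came without S06R at day 1 and between days in the effect, without S08L at day 2, without S22L at day 5 and without S33L at day 9 and for day 9 minus day 1.

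An estimated correlation took all 26 lists that passed over all days past the threshold. Adjusted p was 0.122 for TGF-beta, injury, proximal tubule, thick ascending limb, distal convoluted tubule, macrophages, chemokines, p53 targets, fatty acid oxidation, oxidative phosphorylation, the tricarboxylic acid cycle and the renin-angiotensin system. It was 0.140 for fibroblasts and immediate early genes, 0.149 for matrix remodelling and neutrophils, 0.155 for matrix and interferon, 0.173 for principal and intercalated cells, 0.184 for complement, 0.221 for Wnt regulators, 0.259 for MHC class II, 0.331 for T and NK cells, 0.380 for urothelium and 0.420 for the cell cycle. Fry, which asks only whether the genes of a list move one way, called podocytes (5.7e-06), B cells (0.0171), NRF2 (0.0142) and glycolysis (0.0142) as well.

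Quantile normalization ended the calls of the thick ascending limb (0.0560), principal cells (0.391) and the renin-angiotensin system (0.121), and leaving out the 4 doubted arrays that of the urothelium (0.0920). It turned the direction of lists that passed in neither form, the endothelium (0.0610), adipose tissue (0.617) and red blood cells (0.529). Adipose tissue also turned with zeros kept (0.888) and the sex-specific list with the Xist covariate (0.539). Over the replicates left out in turn the adjusted p ran from 0.582 to 0.978 for adipose tissue, which turned without S04L, S32L and S38L, from 0.623 to 0.987 for the endothelium, which turned without S03 and S21L, and from 0.0307 to 0.963 for the adrenal list. The adrenal list passed without S03 and turned without S06R. Among genes, Kap (0.030) and Umod (0.12) turned with quantile normalization over all days, and 1 of 13 probes of Ighm gave -1.10 at day 9 without passing. No paired analysis was possible because the groups share no replicate numbers.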

Other observations

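The genes of the next 2 paragraphs outside the lists were chosen after their values were seen, as was the last of the 4 relations, added when the other 3 were known; the regroupings were set beforehand.

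Over all days Krt18 and Krt19, keratins of simple epithelia, rose by 2.15 ± 0.14 and 2.73 ± 0.20, Sox9, a transcription factor of repairing tubules, by 2.72 ± 0.26, and Cp, ceruloplasmin, a copper-binding ferroxidase, by 2.71 ± 0.11. Ppargc1a, a coactivator of mitochondrial genes, gave -0.94 ± 0.13, Hnf4a, a regulator of proximal tubule genes, -0.51 ± 0.11 and Vegfa, an endothelial growth factor, -0.72 ± 0.10, each past the limma threshold, although 2 of the 3 probes of Hnf4a, at -0.23 and -0.34, did not pass by themselves.

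In the glomerulus, the podocyte list passed at day 1, where 0 of 13 measured rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0435, and adjusted p = 0.169 with an estimated correlation). It did not pass at the other days, but its difference between day 9 and day 1 did not pass either (camera adjusted p = 0.854). Over all days Clic5 and Podxl, of the podocyte cytoskeleton and surface, gave -0.81 ± 0.11 and -0.53 ± 0.10, while Kirrel, of the slit diaphragm, rose by 0.68 ± 0.13. Of the endothelial list Kdr and Tek, receptors of VEGF and angiopoietin, gave -0.38 ± 0.12 and -0.37 ± 0.13, and the list median was -0.06. Both lost their calls with quantile normalization (-0.08 for Kdr and -0.23 for Tek) and with the arrays marked L alone (-0.34 and -0.37). Kdr also lost it with 4 arrays left out (-0.31) and on 6 of its 10 probes by themselves, and Tek on 1 of 2 probes and without S03R, S05L, S06R, S08L, S21L, S22L, S30L or S33L (-0.36 to -0.27). Among 7265 probes that name no gene or several, tested by themselves with limma, 1372 were called up and 1377 down over all days.

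The mice were of both sexes. At day 2 Xist, the X-inactivation RNA of females, was below 0 on every array, from -6.87 on S04L to -5.49 on S39R, and at day 9 it was below 0 on S09L alone (-6.06 against 2.05 to 2.49 on the others). On sham array S08L the Y-linked gene Eif2s3y stood at 0.04, between 2.18 on S39R and -7.07 on S10L. The arrays S03L and S03R correlated at r = 0.954 across genes, within the range of 0.935 to 0.963 of the 35 other sham pairs, of which 11 lay above it.

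A common degree of injury per kidney could link gene groups among the 13 obstructed replicates, taken as deviations from the mean of their day, with exact permutation p values over 5184 arrangements within days and 4 relations adjusted together. Macrophage and oxidative phosphorylation lists gave r = -0.10 (p = 0.709, adjusted p = 0.709) and rho = -0.22 (p = 0.482, adjusted p = 0.482), and r = 0.018 without the 2 replicates farthest from the median. Macrophage and matrix lists gave r = 0.59 (p = 0.141, adjusted p = 0.188) and rho = 0.51 (p = 0.140, adjusted p = 0.280), and r = 0.40 without the 2. Macrophage and proximal tubule lists gave r = 0.36 (p = 0.120, adjusted p = 0.188) and rho = 0.29 (p = 0.360, adjusted p = 0.480), and r = 0.31 without them. Matrix and oxidative phosphorylation lists gave r = -0.46 (p = 0.0442, adjusted p = 0.177) and rho = -0.63 (p = 0.0299, adjusted p = 0.120), and r = -0.77 without them. None passed after adjustment, so 13 replicates leave such a link open in either direction.

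Of 100 regroupings of the replicates within days, the real one included, 1 called as many genes over all days as the real 9025. The highest of the others called 3. A share of 1 in 100 is the smallest that this number of regroupings can give. Of 100 regroupings of the obstructed replicates over the days, 1 called as many as the real 5659, again the smallest share possible. The others had a median of 0, but the highest of them called 2810.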
